A study of Mus musculus with 8 samples.

How the data were processed

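The series holds 8 expression arrays of 1 immortalized mouse cell line, called cell line 2 in the labels, which had been transduced either with a vector carrying Plag1 or with the empty vector. Each vector was represented by 2 sublines, numbered 1 and 2, and each subline by 2 arrays, lettered A and B, so that each group held 4 arrays. Per the labels' protocols, cells were grown in DMEM with 10% fetal calf serum, thrombopoietin (Tpo) and kit ligand (KL), total RNA was extracted with Trizol and cleaned on columns, and biotin-labelled cRNA was made by the standard Affymetrix procedure. The labels do not say whether the sublines came from separate transductions or whether the letters mark separate cultures, days or hybridizations, so p-values measure the spread between these arrays and sublines, part of which may be technical.

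The values came from the deposited series value table of 45101 probe sets, whose unit is a linear intensity per probe set, in each array's own column. How the authors summarized and normalized the intensities is not given in the sources used here. The deposited intensities were not fully equalized between arrays: the 75th percentile lay between 228 and 266, and the median between 85.3 and 96.6. By a rule fixed before the data were examined, the intensities were therefore quantile normalized, 16 was added and the log2 was taken. A log2 difference on this scale understates the change of dim probe sets. The 64 Affymetrix control probe sets were left out of the comparisons, and so was 1 probe set that held an impossible intensity of 32100000000 on the array empty vector subline 1 B, while its highest other intensity was 20.1. This left 45036 probe sets. No filter on level was applied. The number of arrays limits the precision of every value.

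Plag1 and empty vector arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all 45036 probe sets and a threshold of adjusted p under 0.05. The 2 arrays of a subline were tied as a random block by duplicateCorrelation. The consensus correlation was -0.43, a negative value, because arrays A and B of a subline lay on opposite sides of their group mean. Sublines 2 and 1 of each vector were compared in a limma model with 1 mean per subline, fitted to all 8 arrays, so that the spread between arrays A and B was the only error. Errors of log2 differences are standard errors (SE) from these fits. Means of groups are given with the standard deviation (SD) over 4 arrays.

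Samples were checked for pairing. After the group means were removed, Plag1 and empty vector arrays of the same subline number and letter correlated across probe sets at r = 0.43 to 0.55, above the limit of 0.1 set for calling arrays paired. Arrays that shared only the letter correlated as closely (r = 0.40 to 0.55), and arrays that shared only the subline number did not (r = -0.55 to -0.46). The letter therefore carried the pairing. It accounted for 50.2% of the variation between arrays (1 degree of freedom). The vector accounted for 13.3% (1 degree of freedom), sublines within a vector for 15.3% (2) and the rest for 21.1% (3). These shares are not divided by their degrees of freedom. Because both groups are present in each letter, the comparisons were also run with the letter as a block and within each letter.

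Probe sets were named through the platform annotation, in which 34945 of the tested probe sets had 1 gene symbol, 932 had several and 9159 had none, and through the RefSeq gene table of assembly GRCm38.p6, which was used for names only and held 34741 of the 34945 by their Entrez identifier. Names came from probe sets with 1 symbol. The files name no genome build, so no coordinates are given. Of the probe sets annotated to a gene alone, the one with the highest mean level stood for the gene, which gave 18193 genes. Named genes followed a rule fixed before the data were examined. Plag1, Plagl1, Plagl2, Igf2, Mecom, Gata1, Kit and Mpl were always to be named. In the comparison of vectors, the rule took the 12 genes that rose most and the 12 that fell most among those past the threshold, fully separated between the groups, with a mean in the higher group at or above the median of all probe sets (log2 level 6.75). In each comparison of sublines it took up to 5 genes in each direction, and in each list up to 4 members past the threshold, or 2 if none passed. Mpl had no probe set annotated to it alone and was not analysed here. Genes chosen after their values were seen are marked as such where they appear.

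Gene lists were fixed before the data were examined: 23 lists of 490 genes, of which 454 were measured. They cover megakaryocytes and platelets, erythroid cells, mast cells and basophils, neutrophils, monocytes and macrophages, lymphoid cells, fibroblasts and stroma, stem and progenitor cells, reported PLAG family targets and imprinted genes, insulin-like growth factor and PI3K signalling, cyclins and CDK inhibitors, DNA replication, mitosis, MYC and ribosome biogenesis, interferon response, antigen presentation, p53 targets, the BCL2 family, WNT targets, JAK-STAT and MAPK feedback, glycolysis and hypoxia, cholesterol synthesis, and heat shock with the integrated stress response. They were tested with limma's cameraPR on the moderated statistics with a preset correlation between genes of 0.01, with adjustment over the 23 lists, beside the same test with a correlation estimated per list and fry, which tests whether the members of a list move on balance one way. The camera tests were also run between the sublines of each vector, where the estimated correlation was added after the data had been seen.

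The fits were tested on simulated data with the real probe set means, letter differences and spreads, over 45036 probe sets. In the comparison of vectors, 75% of 100 changes of 1 log2 unit and 97% of 100 changes of 2 log2 units were called, beside 54 probe sets that had not been changed. With the letter as a block the shares were 79% and 96%, with 33 unchanged probe sets called, and with the arrays of each subline averaged they were 39% and 89%, with 1. In the comparison of sublines within Plag1, 75% of 100 changes of 3 log2 units were called without the letter block and 96% with it. Besides these, 9 and 69 other probe sets were called. Each simulated subline also carried random differences of its own, so these need not be false calls. In the gene list test a shift of 0.8 added to the erythroid list was recovered (mean 0.82) and 0 of the other 22 lists passed. The simulated spreads were drawn independently for each probe set, so the genes of a list shared no random differences. In the real arrays they did: the estimated correlation of the megakaryocyte and platelet list was 0.285. The simulation therefore cannot show how often lists are falsely called in the real arrays. Alternatives covered how arrays were tied, the replicate block, each letter alone, the scaling, the pseudocount, a filter on dim probe sets, the prior variance, a minimum fold change, the averaging of probe sets, the correlation within lists, and the removal of each array and each subline. Among the 64 control probe sets, 0 differed between the vectors past the threshold in limma, and 1 did at an unadjusted p under 0.05.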

Results

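Plag1 encodes a zinc finger transcription factor, and the title of the series places it beside Evi1 overexpression and a Gata1s mutation in M7 (megakaryoblastic) leukaemia. The arrays address what Plag1 changes in an immortalized cell line kept in thrombopoietin, the growth factor of the megakaryocyte lineage, and kit ligand. RNA levels were measured on 8 arrays of cell line 2: 4 arrays of cells with Plag1 and 4 of cells with the empty vector, in each case 2 sublines with arrays A and B. Median intensities lay between 85.3 and 96.6 over the arrays before scaling. The letter separated the arrays more than the vector did. Pairs of arrays of the same letter correlated at r = 0.969 to 0.986 across probe sets, and pairs of different letters at r = 0.942 to 0.958 (genes are not independent replicates).

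The transduced gene was checked first. At the probe set annotated with its RefSeq messenger RNA, Plag1 measured 7.54 ± 0.47 (log2 level, SD, n = 4) in the Plag1 arrays and 6.51 ± 0.15 in the empty vector arrays, a rise of 1.03 ± 0.18 (SE; limma adjusted p = 0.032), and all 4 Plag1 arrays lay above all 4 empty vector arrays. The call did not hold with the arrays of each subline averaged (adjusted p = 0.055) or without Plag1 subline 2 A (0.88, adjusted p = 0.055), empty vector 1 A (1.00, 0.103), 2 A (1.10, 0.087), 1 B (0.96, 0.118) or 2 B (1.05, 0.105). It also did not hold with the arrays taken as independent (adjusted p = 0.21) or within letter A (0.65, adjusted p = 0.69). The brighter Plag1 probe set, which represents the gene under the rule for names, differed by 0.04 ± 0.17 (adjusted p = 0.97). The other PLAG family members did not pass the threshold: Plagl1 differed by 0.06 ± 0.10 (adjusted p = 0.91) and Plagl2 by -0.23 ± 0.16 (adjusted p = 0.67). Mecom, the gene of Evi1, was bright in both groups, at 11.42 ± 0.33 with Plag1 and 11.51 ± 0.14 with the empty vector. Gata1, the transcription factor of megakaryocytes and red cells, measured 9.97 ± 0.57 with Plag1 and 10.43 ± 0.66 with the empty vector (adjusted p = 0.53). Kit, the receptor of kit ligand, differed by 0.12 ± 0.12 (adjusted p = 0.82).

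**Figure D1:**
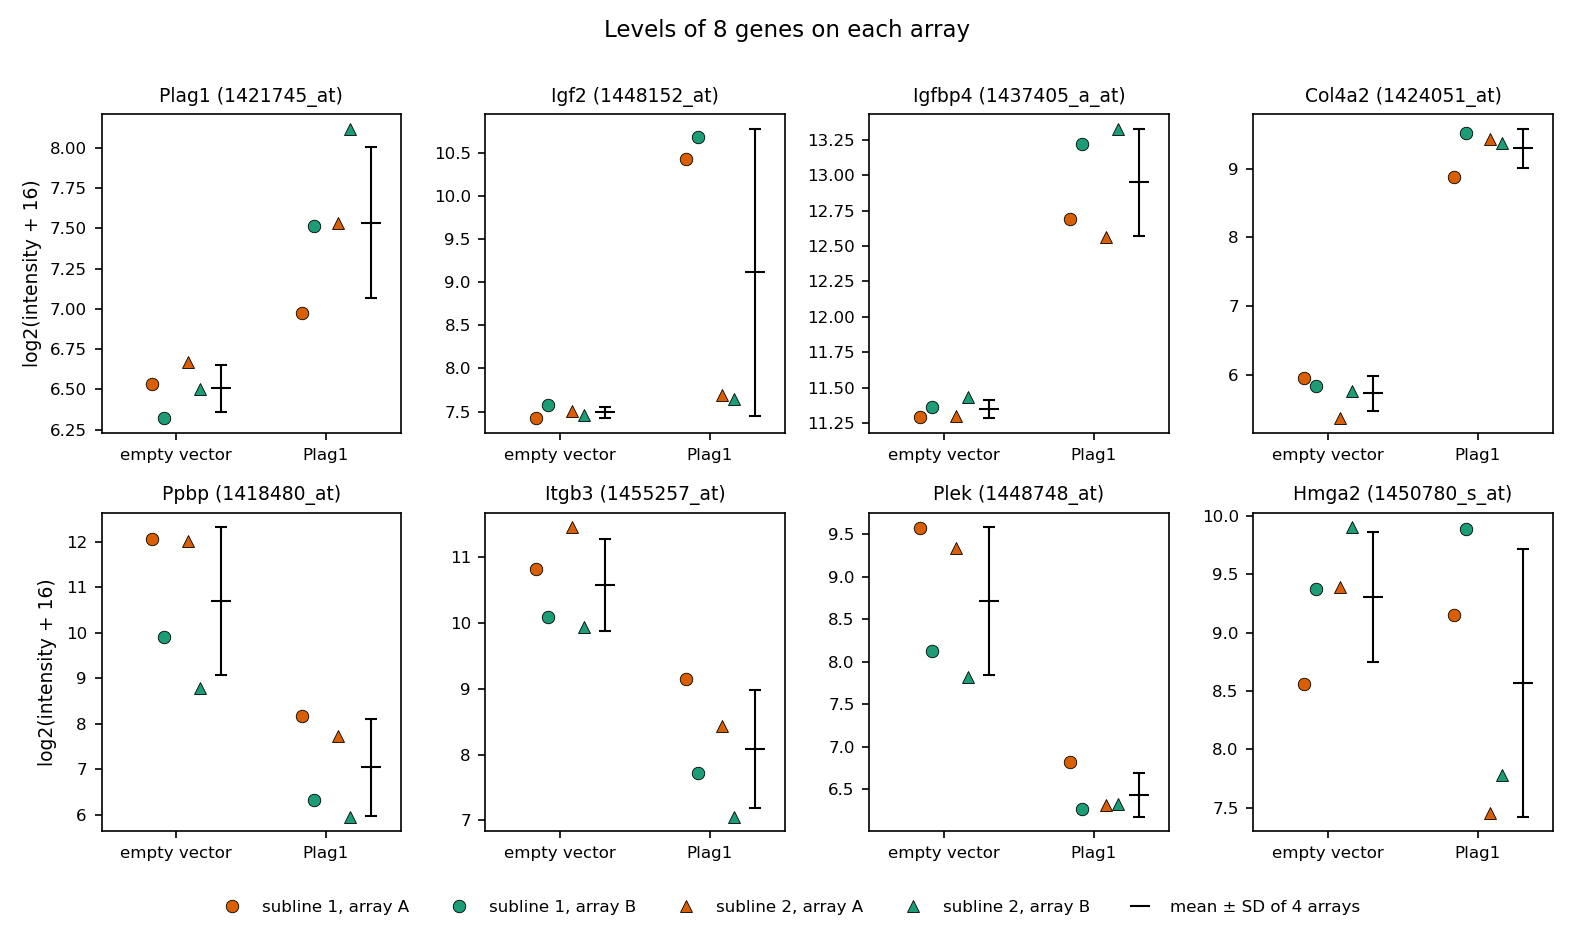
Level of 8 genes on each array, as log2(intensity + 16), for empty vector and Plag1; circles and triangles are sublines 1 and 2, orange and green are arrays A and B, and the bar is the mean ± SD of 4 arrays. Col4a2 lay at 9.30 ± 0.28 with Plag1 and 5.73 ± 0.25 with the empty vector, Ppbp at 7.05 ± 1.07 and 10.70 ± 1.62, and Igf2 was high on the arrays of Plag1 subline 1 alone.

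The comparison of vectors asked which genes differ between cells with Plag1 and cells with the empty vector. Col4a1 and Col4a2, which encode type IV collagen chains of basement membranes, were among the 12 genes that rose most, and 3 genes of platelet proteins, Ppbp, Itgb3 and Plek, were among the 12 that fell most. Col4a2 rose by 3.57 ± 0.14 on the log2 scale (adjusted p = 8.0e-06), and its neighbour Col4a1 by 2.44 ± 0.13 (adjusted p = 5.5e-05). Igfbp4, which binds insulin-like growth factors, went from 11.35 ± 0.06 to 12.95 ± 0.38, a rise of 1.60 ± 0.11 (adjusted p = 0.00017), and all 6 of its probe sets rose, by 1.43 to 1.70. In all, limma called 353 of 45036 probe sets, of which 237 were higher and 116 lower with Plag1. This rests on the negative correlation of -0.43 between arrays of a subline: with the 8 arrays taken as independent 53 probe sets passed, and 14 of the 34 called genes named here kept their call. By representative probe set, 107 genes rose and 57 fell of 18193. All 353 pointed the same way within letter A and within letter B, and 340 had all 4 Plag1 arrays beyond all 4 empty vector arrays. Over all probe sets 1524 (3.38%) were separated in this way. The share would be 2.86% by chance if all 8 arrays were exchangeable. They were not, because the letter, present on both sides, spread the arrays of each group. The 2.86% is therefore not a fair measure of chance here.

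Besides the collagens, the 12 genes that rose most held several enzymes and cell surface or cytoskeletal genes. The aldo-keto reductase Akr1c13 rose by 3.32 ± 0.52 (adjusted p = 0.022), the heat shock transcription factor Hsf4 by 2.97 ± 0.34 (adjusted p = 0.0048) and the phospholipase C-like gene Plcl2 by 2.60 ± 0.29 (adjusted p = 0.0042). Tgm2, a protein-crosslinking transglutaminase, rose by 2.42 ± 0.35 and the surface glycoprotein gene Thy1 by 2.38 ± 0.25. The others were Fcho1 (2.56), Ica1l (2.56), the ketone body enzyme Bdh1 (2.27), the actin-bundling gene Espn (2.27) and Basp1 (2.15), each with an adjusted p of 0.039 or below. The calls of Akr1c13, Ica1l, Tgm2, Bdh1 and Espn each ended without 1 or more of empty vector arrays 1 A, 2 A, 1 B and 2 B, that of Ica1l also without Plag1 subline 2 A and that of Espn also without Plag1 2 B, with an adjusted p of at most 0.127 (Ica1l without empty vector 1 B). The same 5 calls ended with the arrays taken as independent (adjusted p of 0.081 for Tgm2 to 0.427 for Espn), as did that of Myh10. Within letter A, Akr1c13, Hsf4, Ica1l, Tgm2, Thy1 and Espn missed the threshold (adjusted p of 0.052 for Tgm2 and Thy1 to 0.468 for Ica1l). Probe sets of a gene did not always move together. Tns1, chosen after its values were seen, differed by 0.31 ± 0.09 at its brightest probe set (adjusted p = 0.22), whereas the other 2 probe sets of the gene rose by 4.06 ± 0.18 and 3.30 ± 0.17. Myh10, a non-muscle myosin heavy chain also chosen after its values were seen, rose by 2.08 ± 0.21 (adjusted p = 0.0022). A dim second probe set of Myh10 was at 0.34 (adjusted p = 0.28), and that of Bdh1 at 0.96 (0.092). Other probe sets of Tgm2 missed the threshold at 1.38 (0.097) and 0.55 (0.085), while those at 2.15, 2.66 and 2.62 passed.

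Of the 12 genes that fell most, 3 encode platelet proteins. Ppbp, the precursor of a platelet chemokine, fell by 3.66 ± 0.50 (adjusted p = 0.012). Itgb3, the beta chain of the platelet fibrinogen receptor, fell by 2.49 ± 0.32 (adjusted p = 0.0078). Plek, the gene of pleckstrin, a substrate of protein kinase C in platelets, fell by 2.28 ± 0.24 (adjusted p = 0.0029). Scin, an actin-severing protein gene, fell by 2.47 ± 0.21 (adjusted p = 0.00071) and Myom1 by 1.63 ± 0.10 (adjusted p = 8.2e-05). The remaining changes were those of Pick1 (-1.94), the lectin receptor gene Clec7a (-1.67), Gpr174 (-1.40), Bmp2k (-1.36), the focal adhesion gene Zyx (-1.13), the progenitor antigen Cd34 (-1.07) and the phosphate transporter gene Slc20a1 (-1.03). Not every other probe set fell: a dim second one of Pick1 differed by 0.07 ± 0.10 (adjusted p = 0.89). The others of Bmp2k were at -0.88 (adjusted p = 0.11) and -0.23 (0.49). The second of Gpr174 was at -1.49 (0.0048). Those of Slc20a1 were at -0.69 (0.070) and 0.09 (0.86), and the dim second of Zyx was at -0.82 (0.075). The call of Ppbp ended without empty vector 2 A (adjusted p = 0.051). Those of Clec7a, Gpr174, Bmp2k, Zyx and Cd34 each ended without 2 or more of the empty vector arrays, Gpr174 and Cd34 also without Plag1 subline 2 B and Cd34 without Plag1 1 B, with an adjusted p of at most 0.155 (Cd34 without empty vector 2 B). With the arrays taken as independent the calls of Ppbp (adjusted p = 0.215), Itgb3 (0.143) and Plek (0.081) ended, and those of Clec7a, Gpr174, Bmp2k, Zyx, Cd34 and Slc20a1. Within letter A, Pick1, Clec7a, Gpr174, Bmp2k, Zyx, Cd34 and Slc20a1 missed the threshold (adjusted p of 0.053 for Slc20a1 to 0.906 for Cd34), and within letter B so did Clec7a (0.091). Rap1b, a small GTPase gene of platelets chosen after its values were seen, fell by 0.98 ± 0.09 (adjusted p = 0.0014).

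The megakaryocyte and platelet list was lower as a group. Of its 28 measured members, 9 fell and 1 rose past the threshold, and 18 did not pass. Adjusted over the list alone, 11 fell and 2 rose. The mean difference was -0.46 within letter A and -0.53 within letter B. The median difference over the 28 members was -0.29, and the list passed the camera test (adjusted p = 3.7e-12), but not with a correlation estimated from these arrays (adjusted p = 0.109 with an estimated correlation). In the fit with the letter as a block the list passed with both correlations (adjusted p = 7.2e-21 with the preset correlation and adjusted p = 0.00032 with an estimated correlation). The fry test, which does not compare the list with other genes, gave an adjusted p of 0.26. After Ppbp, Itgb3 and Plek, the member with the smallest adjusted p was Rab27b, a gene of platelet granule secretion, which fell by 0.79 ± 0.13. Its other probe sets were at -1.16 (adjusted p = 0.0012), -1.13 (0.0078) and -1.14 (0.0062). Pf4, the platelet factor 4 gene chosen after its values were seen, measured 10.37 ± 1.43 with Plag1 and 12.53 ± 0.76 with the empty vector, a difference of -2.16 ± 0.42 that missed the threshold (adjusted p = 0.057) and passed with the letter as a block (adjusted p = 0.00056). The member that rose was Vwf, the von Willebrand factor gene, also named after its values were seen, by 1.49 ± 0.28 (adjusted p = 0.046). The call of Rab27b at its brightest probe set ended without any 1 of the 4 empty vector arrays (adjusted p of at most 0.089, without 2 A). That of Vwf ended without empty vector 1 A, 1 B or 2 B or Plag1 subline 2 A or 2 B (at most 0.146, without empty vector 1 B). Both calls also ended with the arrays taken as independent (adjusted p = 0.32 each) and within letter A (0.43 and 0.36). The platelet glycoprotein genes Gp5, Gp6 and Gp9, chosen after their values were seen, differed by 0.07, 0.05 and -0.21, with adjusted p of 0.94, 0.95 and 0.78.

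**Figure D2:**
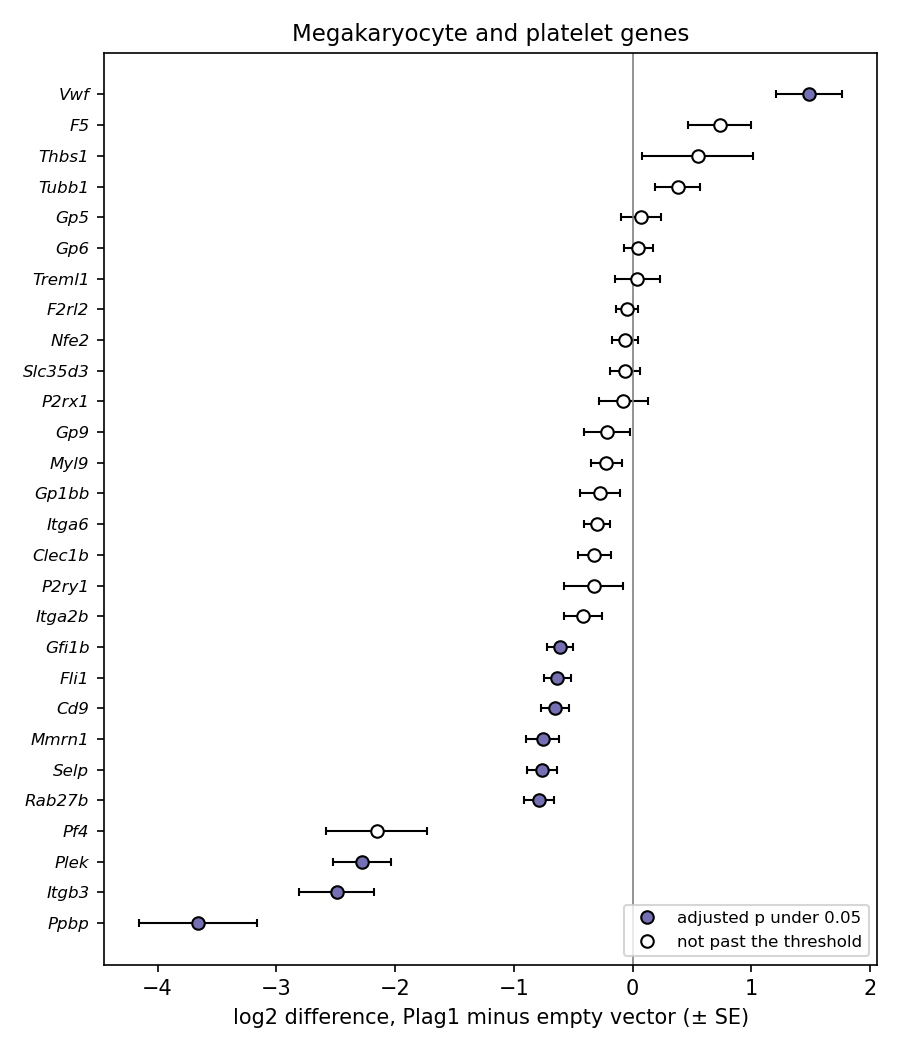
Log2 difference, Plag1 minus empty vector, with its SE for the 28 measured genes of the megakaryocyte and platelet list; filled points have an adjusted p under 0.05 and open points do not. The differences run from -3.66 for Ppbp to 1.49 for Vwf.

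Lists of other blood and stromal cells did not pass the camera test. In the erythroid list 1 of 24 members fell, Hemgn by 0.70 ± 0.13 (adjusted p = 0.049), and the list's adjusted p was 0.36. Adjusted over the list alone, 1 erythroid gene fell and 1 rose. In the list of fibroblasts and stroma 1 of 19 rose, Thy1, and the list's adjusted p was 0.65. Adjusted over the list alone, 3 genes of fibroblasts and stroma rose and 1 fell. In the stem and progenitor list 2 of 23 fell, Lmo2 by 0.91 ± 0.16 (adjusted p = 0.035) and Cd34, with an adjusted p of 0.55 for the list and 3 that fell adjusted over the list alone. No member passed in the lists of mast cells and basophils (adjusted p = 0.16), neutrophils (adjusted p = 0.49), monocytes and macrophages (adjusted p = 0.65) or lymphoid cells (adjusted p = 0.78). The calls of Hemgn, Lmo2 and Cd34 ended without Plag1 subline 2 B or without several of the empty vector arrays, with an adjusted p of at most 0.174 (Hemgn without empty vector 2 B). Those of Hemgn and Lmo2 also ended with the arrays taken as independent (adjusted p = 0.57 and 0.35) and within letter A (0.160 and 0.130), and that of Lmo2 within letter B (0.067). The largest differences in these 4 lists were those of the granzyme gene Gzmb, at -1.79 ± 0.58 (adjusted p = 0.27), and the zinc finger repressor gene Gfi1, at 1.58 ± 0.32 (adjusted p = 0.071, and 0.028 with the letter as a block). Gfi1, in the neutrophil list, passed when adjusted over the list alone, where no other member of these 4 lists passed.

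The list of reported PLAG family targets and imprinted genes passed upward (adjusted p = 0.015), although 1 of its 18 members was called, and it did not pass with a correlation estimated from the arrays (adjusted p = 0.18 with an estimated correlation). That member was Cdkn1c, the imprinted gene of the CDK inhibitor p57, which rose by 1.13 ± 0.10 (adjusted p = 0.0011, and 0.21 within letter A). Adjusted over the list alone, 2 rose. The list did not pass within letter B (adjusted p = 0.26), without Plag1 subline 2 A (adjusted p = 0.059) or without empty vector 2 B (adjusted p = 0.064). Igf2, an imprinted growth factor gene in the same list, measured 9.12 ± 1.67 with Plag1 and 7.49 ± 0.07 with the empty vector, a difference of 1.63 ± 0.65 that missed the threshold (adjusted p = 0.39) and passed without Plag1 subline 2 A (2.63, adjusted p = 0.041).

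The mitosis list passed downward with 0 of 23 members called (median -0.20, adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.83 with an estimated correlation). It also did not pass within letter B (adjusted p = 0.26), nor without Plag1 subline 2 A (adjusted p = 0.90), Plag1 2 B (0.110), empty vector 1 A (0.108), 1 B (0.151) or 2 B (0.057). Aurkb and Cenpa, kinase and centromere genes of mitosis, had differences of -0.38 ± 0.19 and -0.38 ± 0.18. In the list of insulin-like growth factor and PI3K signalling 1 of 24 members rose, Igfbp4 (adjusted p = 0.36 for the list), and in that of cyclins and CDK inhibitors 1 of 21, Cdkn1c (adjusted p = 0.49), with 1 risen and 1 fallen adjusted over the list alone. In the list of JAK-STAT and MAPK feedback 1 of 24 fell, the kinase gene Pim2 by 0.98 ± 0.12 (adjusted p = 0.0078, and 0.058 within letter B), and the list's adjusted p was 0.28. Adjusted over the list alone, 1 rose and 1 fell.

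No member was called and no list passed for DNA replication (adjusted p = 0.39), MYC and ribosome biogenesis (adjusted p = 0.54), interferon response (adjusted p = 0.54), antigen presentation (adjusted p = 0.90), p53 targets (adjusted p = 0.36), the BCL2 family (adjusted p = 0.99), WNT targets (adjusted p = 0.81), glycolysis and hypoxia (adjusted p = 0.12), cholesterol synthesis (adjusted p = 0.31) or heat shock with the integrated stress response (adjusted p = 0.65). Adjusted over the list alone, 2 interferon genes rose and 3 fell, and no gene of the other 9 lists passed. For fibroblasts and stroma, stem and progenitor cells, insulin-like growth factor and PI3K signalling, cyclins and CDK inhibitors, and WNT targets the median and the mean difference had opposite signs, and for the BCL2 family both were above 0 while the test pointed down. When the letter was a block 5 more lists passed: DNA replication (adjusted p = 0.0076), MYC and ribosome biogenesis (adjusted p = 0.043) and glycolysis and hypoxia (adjusted p = 0.0010) downward, and p53 targets (adjusted p = 0.0075) and JAK-STAT and MAPK feedback (adjusted p = 0.0066) upward. None of these 5 passed with an estimated correlation in the same fit. Single members were called in that fit too: 2 p53 targets rose and 1 fell, and 1 gene each fell in the lists of mitosis, interferon response, WNT targets, and glycolysis and hypoxia. In the same fit 3 genes rose and 1 fell in JAK-STAT and MAPK feedback, 2 rose and 1 fell in cyclins and CDK inhibitors, 3 rose in fibroblasts and stroma, and 1 rose and 1 fell in the erythroid list.

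The count of called probe sets also depended on how the letter was handled. In the fit with the letter as a block 771 probe sets passed, 420 higher and 351 lower with Plag1, and they held 320 of the 353. Within letter A alone 61 passed and within letter B alone 340, of which 38 of the 353 were called in both. Averaging the arrays of each subline gave 334, of which 220 were among the 353. Leaving out 1 array gave 1224 without Plag1 subline 1 A, 541 without Plag1 2 A, 163 without empty vector 1 A, 134 without 2 A, 119 without 1 B and 104 without 2 B. In simulated data with 200 true changes the fit also called 54 unchanged probe sets, more than its threshold allows, and the fit with the letter as a block called 33.

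The comparison of sublines asked how far cells with one vector differ among themselves. In Plag1 cells Igf2 gave 1 of the 2 calls. It measured 10.43 and 10.69 on arrays A and B of Plag1 subline 1, and 7.70 and 7.65 on those of Plag1 subline 2, where it was near the 7.49 ± 0.07 of the empty vector arrays. As a mean intensity this was 1500 in subline 1, 188 in subline 2, and 165 and 163 in the empty vector sublines. Subline 2 was lower by 2.89 ± 0.20 on the log2 scale (limma adjusted p = 0.023, and 7.6e-06 with the letter as a block). The call did not hold on the values as deposited (-2.85, adjusted p = 0.088) or without any 1 array, where the difference stayed between -3.02 and -2.76 and the adjusted p ran from 0.157 to 0.764. A second, dim Igf2 probe set differed by -0.82 ± 0.40 (adjusted p = 1.00). The other call was a dim probe set of Fgd4, chosen after its values were seen, which was higher in subline 2 by 2.69 ± 0.18 (adjusted p = 0.023). Its other probe sets did not pass in this fit. These 2 of 45036 were all that limma called, with 1088 at an unadjusted p under 0.05, and 0 were called when any 1 array was left out, whichever it was.

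Lists were also compared between the Plag1 sublines. The monocyte and macrophage list was higher in subline 2 (median 0.19, adjusted p = 0.00035), also with an estimated correlation (adjusted p = 0.00021), a test added after the data had been seen. The lists of megakaryocytes and platelets (median 0.26, adjusted p = 0.00035) and erythroid cells (median 0.11, adjusted p = 0.026) were higher and those of mitosis (median -0.29, adjusted p = 0.00035) and of mast cells and basophils (adjusted p = 0.026) lower, but none of these 4 passed with an estimated correlation (adjusted p = 0.57, 0.57, 0.57 and 0.35). The list of mast cells and basophils had a median of 0.0007 and a mean of -0.21, and missed the threshold with the letter as a block (adjusted p = 0.053), where DNA replication (adjusted p = 0.027) and antigen presentation (adjusted p = 0.0055) passed downward. Neither of these passed in that fit with an estimated correlation (adjusted p = 0.77 and 0.49 with an estimated correlation). Between the empty vector sublines no list passed.

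Taking the letter as a block, which removes the difference between arrays A and B from the error, limma called 140 probe sets between the Plag1 sublines, 61 higher and 79 lower in subline 2. In simulated data this fit called 96 of 100 added changes and 69 other probe sets. The simulated sublines also differed at random, so these 69 need not be false calls, and the rate of false calls was not measured. The genes in this paragraph were chosen after the values were seen. Hmga2, an architectural chromatin protein gene, was lower in subline 2 at its brightest probe set (log2 difference -1.91, adjusted p = 0.00018 with the block) and at 2 others, while a dim probe set differed by -0.21. Akr1c12 was lower in subline 2 (-2.89), as were the granzyme gene Gzmb (-2.42), Dipk1b (-2.34) and the selenium transport protein gene Selenop (-2.29). Higher in subline 2 were Eda2r (2.57), the myeloid integrin gene Itgam (2.55), the chemokine gene Ccl6 (2.17), the coagulation factor gene F13a1 (1.82) and the haemoglobin gene Hbb-b2 (1.81). Without the block none of these passed.

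Between the sublines with the empty vector limma called 0 probe sets, with 694 at an unadjusted p under 0.05. The block gave 6, 2 higher and 4 lower in subline 2. They included Tpm4, a tropomyosin gene, at -2.03 (adjusted p = 0.0034 with the block), and Selenop at -1.96 (adjusted p = 0.035 with the block). Both were also lower in subline 2 of Plag1, at -1.48 and -2.29 (adjusted p = 0.0051 and 0.0016 with the block). The larger number of calls within Plag1 does not by itself show that its sublines differed more. A test of that difference called 0 probe sets without the block, with 864 at an unadjusted p under 0.05, and 22 with it, where the rate of false calls was not simulated.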

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

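Chosen only after the result was seen were the tests of Igf2, the tests of a lower share of megakaryocytic cells, the test of RNA degradation and the splits for the megakaryocyte list.

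In 8 of 164 groups of 4 arrays of the named genes, 1 array stood apart from the other 3 by more than Dixon's limit, and chance alone gives about 8.2. Array A of empty vector subline 2 did so for Vwf (11.06, nearest other 9.88), Tns1 (9.74, nearest 9.57) and Aurkb (8.75, nearest 9.16). Array A of Plag1 subline 1 did so for Plek (6.82, nearest 6.32) and Gpr174 (6.58, nearest 5.81), array B of the same subline for Col4a1 (9.79, nearest 9.14) and Lmo2 (11.55, nearest 10.86), and array A of Plag1 subline 2 for Tns1 (10.19, nearest 9.84). Plek and Gpr174 stayed below, and Col4a1 above, every array of the empty vector.

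The subline difference in Plag1 cells departed from that in empty vector cells, in a test of the difference itself with the letter as a block, for 8 probe sets of the genes named here. False calls were not measured in simulated data for this test or for the comparison of Plag1 sublines with the same block. None passed without the block, where the smallest adjusted p was 0.30. Subline 2 minus subline 1, Plag1 minus empty vector, was -2.87 for Igf2 (limma adjusted p = 0.00020 with the block), -3.31, -2.59 and -2.29 for the probe sets of Hmga2, -2.69 for Dipk1b, 3.27 for Itgam, 3.19 for Eda2r and 2.62 for Fgd4.

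Igf2 was high in Plag1 subline 1 and near the empty vector level in Plag1 subline 2. A fault of a single array is argued against, since both arrays of subline 1 lay above the other 6, by at least 2.74 log2 units. Less Plag1 transcript in subline 2, which predicted a lower level there in both letters, was not seen. At the probe set that rose with the vector, Plag1 was higher in subline 2, by 0.56 in letter A and 0.60 in letter B. The difference of 0.58 ± 0.22 (SE with the letter as a block) missed the threshold over all probe sets (adjusted p = 0.53). The brighter Plag1 probe set differed by -0.01 ± 0.17. The direction thus went against this explanation, but without a call it stays open. A fault of the Igf2 probe set stays open too. The second Igf2 probe set was also highest in Plag1 subline 1, at a mean intensity of 96.3. It was at 42.3 in Plag1 subline 2, and at 30.7 and 32.4 in the empty vector sublines. Its difference (-0.82) missed the threshold in limma with the letter as a block (adjusted p = 0.49). Its mean level of 5.91 was under the median of 6.75. A difference between the 2 sublines in how Igf2 responds to Plag1, or in events before or after transduction, also stays open and was not tested.

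The lower megakaryocyte and platelet genes with Plag1 were weighed against 3 explanations. The choice of scaling did not make the difference, since the mean of the list was -0.50 and -0.486 under the other scalings. The list passed the camera threshold in both with the preset correlation, and an estimated correlation was not tried there. The scalings hardly differed: the median shift over all probe sets was -0.0062, 0.0055 as deposited and -0.0115 median-centred. This test could hardly have failed, so it does not exclude another fault of scaling. The letter is argued against: the mean was -0.46 within letter A, where 17 of 28 members were below 0, and -0.53 within letter B, where 21 were. A lower share of megakaryocytic cells stays open. The upper quartile of the members was -0.0257 and the median of the 9 that fell was -0.765, a gap of 0.739. The rule asked for a gap larger than that median fall. Unchanged members could not have met it, so this test cannot decide. Members that did not fall, such as Vwf, limit this explanation without excluding it. A change of gene activity with Plag1 in otherwise similar cells, which the design names, also stays open as a hypothesis.

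Of the 35 splits of the 8 arrays into groups of 4, 2 gave at least the 353 probe sets of the real one: the real split and letter A against letter B, which called 11580 and so points to a structure of the arrays. The share of 2 in 35 does not exclude chance. The highest of the other 33 splits was 1 probe set. Splits that part the arrays of a subline are not on equal terms with the real one, since the subline block then spans both groups. Of the 3 splits that keep sublines whole, the real one alone called as many, and the highest other count was 0. These 3 are too few for a share under 0.05. The real split called 771 with the letter as a block. Among the 8 splits that part every numbered pair, the highest other count was 0 with the block and 0 without it, and 8 splits are too few for a share under 0.05. For the lists, 18 of the 35 splits called at least 3, with up to 9, so that the number of lists past the threshold does not stand out among all splits. Apart from the real one, all of these 18 were unbalanced for the letter. Their lists therefore also carry the difference between arrays A and B, and the share does not measure chance alone. Of the 18 splits with 2 arrays of each letter on each side, 1 called as many, the real one, and 18 are too few for a share under 0.05. For the megakaryocyte list itself, 1 of all 35 splits, the real one, gave a p as small as 1.6e-13, and the smallest in the others was 7.5e-13, in a split that shares 3 of its 4 arrays with the Plag1 group. All 35 do not respect the letter, which carries the pairing. The 18 splits balanced for the letter, where the smallest other p was also 7.5e-13, and the 8 that part every pair, where it was 6.7e-07, are too few for a share under 0.05. The mean shift of the list was larger in 3 other splits (-0.58, -0.55 and -0.51) than in the real one (-0.49).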

How the results depend on the processing

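The alternatives were fixed before the data were examined, except the letter block under other scalings and with left-out arrays and the estimated correlation with the letter block and between sublines, which were chosen after seeing the data. No gene or list past the threshold in the comparison made or in an alternative changed sign between them. Differences that missed it in both did in places: within letter B, the brighter Plag1 probe set was at -0.13, Mecom at 0.05 and Kit at -0.03, against 0.04, -0.09 and 0.12 in both letters. For the comparison of vectors, other scalings, pseudocounts and prior variances gave 302 to 344 probe sets and 3 lists, and averaging the arrays of each subline gave 334, of which 220 were among the 353. The cause of the following changes was not tested unless stated. Treating the 8 arrays as independent gave 53 probe sets and 26 genes in place of 353 and 164. With the letter as a replicate block the counts were 771 and 391, with the 4 numbered pairs as a replicate block 758 and 377, and with subline number and letter as replicate blocks 768 and 388. These blocks take the letter difference out of the error. Letter A alone gave 61 probe sets and 26 genes, with fewer arrays, and a minimum change of 2-fold left 152 and 67 by its construction. Leaving out both arrays of a subline gave 100 probe sets and 41 genes (empty vector subline 1), 88 and 39 (empty vector subline 2), 2089 and 902 (Plag1 subline 1), and 877 and 355 (Plag1 subline 2).

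Leaving out 1 array gave 104 to 1224 probe sets and 50 to 531 genes. The counts that moved by over 1.5 times were 1224 without Plag1 subline 1 A, 541 without Plag1 subline 2 A, and 163, 134, 119 and 104 without empty vector arrays 1 A, 2 A, 1 B and 2 B. The letter block gave 313 to 1831 (1831 without Plag1 subline 1 A, 313 without Plag1 2 B, and 445, 361, 360 and 331 without empty vector 1 A, 2 A, 1 B and 2 B), and 755 and 765 under the other scalings. The number of lists past the threshold, 3, became 10 with averaged arrays, 8 with the letter as a replicate block, 9 with the 4 pairs, 8 with subline number and letter, 7 in letter A, 0 with an estimated correlation, 1 with an estimated correlation and the letter as a replicate block (the megakaryocyte list), and 2 to 5 without 1 array (5 without Plag1 subline 1 A). The megakaryocyte list kept its direction under every alternative run. It passed the camera test under all but the estimated correlation without the block, and missed the threshold in the fry test (adjusted p = 0.26). The mitosis list lost its call within letter B, with an estimated correlation, with the probe sets of a gene averaged, and without Plag1 subline 2 A, Plag1 subline 2 B, empty vector 1 A, 1 B or 2 B, and without both arrays of empty vector subline 1 (adjusted p = 0.41) or Plag1 subline 2 (0.76). The list of PLAG family targets lost it within letter B, with an estimated correlation, among brighter probe sets, and without Plag1 subline 2 A, empty vector 2 B or both arrays of empty vector subline 2 (0.102). Igf2 passed in the comparison of vectors without Plag1 subline 2 A (2.63, adjusted p = 0.041) and without both arrays of that subline (3.07, adjusted p = 1.3e-05).

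Between the Plag1 sublines, 2 probe sets became 140 with the letter as a replicate block, 1 as deposited, 1 with a pseudocount of 1, 1 among brighter probe sets, and 0 with the 4 Plag1 arrays alone or without any 1 array (0 to 0). Between the empty vector sublines, 0 became 6 with the letter as a replicate block and stayed 0 otherwise. Of 34 called genes named here, 34 kept their call with the letter as a replicate block, 33 with averaged arrays (all but Plag1 itself), 14 with arrays taken as independent, 15 in letter A, 31 in letter B and 20 to 34 without 1 array (20 without empty vector 1 B). Simulated data gave more false calls in the fit used here than the threshold allows (54 beside 200 true changes). The letter block also gave them (33 there), and averaged arrays gave 1. Between the simulated Plag1 sublines the letter block called 69 other probe sets beside 100 added changes. Those sublines also differed at random, so false calls were not measured there. Dim probe sets, such as those of Fgd4 and the second of Igf2, lie under the median level and limit what their differences show.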

Other observations

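All tests in this part were chosen after the result was seen, except that of scaling between arrays.

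Arrays A and B differed far more than the vectors did. The genes named in this paragraph were chosen after their values were seen. With a mean per subline, limma called 11980 of 45036 probe sets between the letters, 6073 higher and 5907 lower in letter B. Genes of DNA replication and of ribosome building were higher in letter B. Of 27 DNA replication genes 24 were higher and 0 lower (median 1.26, camera adjusted p = 8.0e-27, and 0.00026 with an estimated correlation), such as the helicase subunit gene Mcm5, at 9.10 ± 0.49 in letter A and 11.31 ± 0.08 in letter B (SD, n = 4 arrays), and the sliding clamp gene Pcna (10.16 ± 0.30 and 12.33 ± 0.16). Of 24 genes of MYC and ribosome biogenesis 20 were higher and 2 lower (adjusted p = 5.5e-24, and 0.00026 with an estimated correlation). Targets of p53 went the other way: 17 of 19 were lower in letter B and 0 higher (median -1.45, adjusted p = 1.6e-30, and 5.6e-06 with an estimated correlation), among them Cdkn1a (12.08 ± 0.18 and 10.22 ± 0.33), Mdm2 (11.85 ± 0.23 and 10.12 ± 0.07) and Pmaip1 (9.89 ± 0.38 and 7.96 ± 0.17). The glycolysis and hypoxia list was also lower in letter B, with 10 of 18 members lower and 1 higher (adjusted p = 3.2e-11, and 0.047 with an estimated correlation), such as Ankrd37 (9.88 ± 0.36 and 6.92 ± 0.42) and Egln3 (11.95 ± 0.32 and 9.22 ± 0.79). The BCL2 family was lower too (adjusted p = 0.00021, and 0.00019 with an estimated correlation). Heat shock with the integrated stress response was higher (0.00021 and 0.00026). Megakaryocytes and platelets (mean -0.42, adjusted p = 0.0016) and antigen presentation (0.0022) were lower, and mitosis (0.0032) was higher. None of these last lists passed with an estimated correlation (0.32, 0.32 and 0.45). A test in limma of whether the effect of the vector differed between the letters called 0 probe sets, with 2329 at an unadjusted p under 0.05. Its power was not simulated, so it does not show that the effects were equal.

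The letters could differ for technical reasons, and 2 were tested. The choice of scaling did not make the differences. Under the other scalings the smallest mean shift of the DNA replication and p53 lists, each in its own direction, was 1.17 log2 units, with both past the threshold. Array medians differed little before scaling (85.3 to 96.6), so this test could hardly have failed. A common factor per array is argued against, since the 2 lists moved in opposite directions. RNA degradation in one letter stays open, since the control probe sets disagree: the 3' to 5' log2 ratio of Actb differed by -0.206 (letter B minus A), at 0.016 to 0.047 against 0.103 to 0.299 in letter A, while that of Gapdh differed by 0.0011. Gapdh ratios lay between -0.193 and -0.153 on all arrays. The ratios of both controls, and their differences between letters, were thus small beside the list shifts of 1.17 or more. These are controls of 2 genes only, so the test cannot decide. The labels do not say what the letter marks, so no biological explanation was tested.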
